A study of Mus musculus with 45 samples.

How the data were processed

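Fetal livers were taken at E15.5 from crosses of VavCre females with males homozygous for a floxed Rpl5 or Rps19 allele, per the labels, genotyped by PCR, treated with emetine (25 µg/mL for 15 min) and sorted with magnetic beads into Kit+ cells and then Ter119+ cells. Cells were pooled by genotype, lysates were spun through 10 to 50% sucrose at 41000 rpm for 2 h, and poly(A) RNA of the cytoplasm and polysome fractions was sequenced with 100 bp reads. The aligner and the counting tool are not given in the sources used here, and the submitters' processing notes name the genome build mm10.

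The deposited table holds log2 values of 13449 genes in 45 libraries, which the authors made by a variance-stabilising transformation of read counts divided by 1 size factor per library. The transformation was inverted, and whole reads were recovered for 100% of the values, with a largest deviation of 7.2e-07 and a tolerance of 1e-06. The size factors were those of the median of ratios over the 2434 genes with reads in all libraries. The lowest deposited value, 2.92263, stands for 0 reads, and the lowest total of a gene was 10 reads. Gene positions are from an annotation table of GRCm38.p6, in which 13245 symbols were found. Among 43 pairs of replicates none were copies, the lowest chi-square per degree of freedom being 22.28.

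Tests were made with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend, two-sided, Benjamini-Hochberg over the genes tested, threshold 0.05) on the deposited log2 values, for genes with a mean normalized count of at least 10. The plan fixed before the data were examined named log2 of a normalized value plus 1, which the deposited scale replaced, so that form became an alternative. Each VavCre group was compared with the floxed group of its own line in the same cell type and fraction, the 4 genotypes sharing 1 estimate of the spread. The difference between the lines is the change with Rpl5 minus the change with Rps19, each with its own control libraries. Ratios and fraction comparisons had the pool as a block. Of the other comparisons, 3 showed correlated differences between libraries of the same replicate number (a correlation over 0.1 in all pairs), which were Rpl5 in Kit+ and Ter119+ cytoplasm and Rps19 in Ter119+ cytoplasm, and their blocked counts stand beside the result. A group of 1 library was assumed to vary like the other groups. With 3 libraries against 3 an exact test of the labels cannot give a p under 0.10, so no such p is given.

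Gene lists were fixed before the data were examined: small-subunit and large-subunit ribosomal proteins without Rps19 and Rpl5, other TOP mRNAs, ribosome biogenesis, p53 targets, integrated stress response, heme synthesis and iron uptake, globins and AHSP, red cell membrane, erythroid transcription factors and Epor, stem and progenitor, G1/S and replication, G2/M, granulocyte and monocyte, macrophage, mast cell and basophil, megakaryocyte and platelet, B-lymphoid, hepatocyte, endothelial and stromal markers, interferon response, immediate early and heat shock, mitochondrially encoded mRNAs, nuclear-encoded oxidative phosphorylation, sex-linked genes and nuclear-retained lncRNAs. A list of snoRNA hosts had no member in the file. Lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists and comparisons of a family, again with an estimated correlation, and with fry, a rotation test. Members were counted after adjustment over all genes and adjusted over the list alone. On polysomes and for ratios, list medians were also placed among 10000 random lists of members of like abundance. Outside the genotype comparisons in cytoplasm the text gives a subset of the lists called. List medians are left out where a member was at 0 in all libraries of a group.

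Named genes were chosen by a rule fixed before the data were examined: 13 genes in every comparison, the 6 with the largest change in each direction whose groups did not overlap and whose higher mean was at least 50, the 4 with the smallest adjusted p of each list, and all genes where 5 or fewer were called. The text names a subset of these, mainly list members, leaving out genes that overlap another gene or have a near-identical copy, such as Rps27. Alas2 and Rpl5, which overlap Apex2 and Dipk1a, were kept. Results of some genes that the rule names are not reported here. Overlaps were counted against the product of the shares of genes called.

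The analysis was tested on simulated data with the depths and spread of these libraries, in which 200 genes were changed, by 0.5, 1 or 2 on the log2 scale. In Kit+ cytoplasm a change of 1 was recovered for 92.5% of the changed genes for Rpl5 and 91% for Rps19, in Ter119+ cytoplasm for 65.7% and 73.1%. On polysomes a change of 1 was recovered for 0% and 5.97% in Kit+ and 0% and 2.99% in Ter119+ cells, and a change of 2 for 16.7% and 33.3% in Kit+ and 28.8% and 30.3% in Ter119+ cells.

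Alternatives planned before the data were examined were a pseudocount of 5, no filter, libraries rescaled to each other, only the groups of a comparison, the block added or removed, and leaving out each library. Added after seeing the data were log2 of the normalized count plus 1, limma voom on the recovered reads, a filter at a mean of 500, a block within each floxed line, and leaving out the libraries under 2 M reads. edgeR and DESeq2, planned for the case that whole reads could be had, were not used, since the deposited unit is log2. Whole reads were recovered all the same, and voom on them stands in for a test on reads. Figures were drawn with matplotlib 3.10.9.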

Results

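Poly(A) RNA of fetal mouse liver at E15.5 was sequenced in 45 libraries, 24 from the cytoplasm and 21 from the polysome fraction of a sucrose gradient. VavCre deletes floxed alleles in blood cells, and the genotypes were Rpl5flox/+ and Rps19flox/+ with or without VavCre. Kit+ cells, which hold stem and progenitor cells, and Ter119+ cells, which are maturing erythroid cells, were taken by magnetic beads. The genotype, cell type and fraction gave 16 groups, of which 14 held 3 libraries, while VavCre Rpl5flox/+ Kit+ polysome held 1 and Rpl5flox/+ Ter119+ polysome held 2. The libraries held 22.9 to 70.1 M reads in Kit+ cytoplasm, 45 to 124 in Ter119+ cytoplasm, 1.01 to 37.6 in Kit+ polysome and 1.02 to 39.8 in Ter119+ polysome. Under 2 M reads were found in 4 of the polysome libraries, and these were Rpl5flox/+ Kit+ replicate 3 (1.81 M), Rps19flox/+ Kit+ replicates 1 and 3 (1.01 and 1.83 M) and VavCre Rpl5flox/+ Ter119+ replicate 3 (1.02 M). Levels are normalized counts with the SD, changes are on the log2 scale with the standard error of the limma fit where one is given, and adjusted p-values are from limma. Values in parentheses after gene symbols are log2 changes, and the counts of a list marked alone are adjusted over that list alone and given where they differ. Each group of 3 was compared with 3 others unless another number is given, and the p-values measure only the spread between these libraries.

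The first question was whether each targeted gene was lower in the libraries of its own genotype. In Kit+ cytoplasm Rpl5 (chromosome 5, 107900508 to 107909005 in the GRCm38.p6 table) was lower with VavCre Rpl5flox/+, at 531 ± 81.3 against 1046 ± 100 in the controls (-0.97 ± 0.15, adjusted p = 0.000287). Rps19 (chromosome 7, 24884592 to 24889811) was lower with VavCre Rps19flox/+, at 12940 ± 1410 against 18040 ± 1990 (-0.48 ± 0.11, adjusted p = 0.00191). That fall was not particular to Rps19. In the same libraries the median of the other small-subunit genes was -0.32, and Rpl5 was 643 ± 135 against 964.6 ± 89.6. In Ter119+ cytoplasm Rpl5 went against the label, at 499.9 ± 47 against 368 ± 83.6 in the controls (0.44 ± 0.16, adjusted p = 0.0278), with overlapping libraries, so these are named below as the libraries labelled VavCre Rpl5flox/+ Ter119+. That call was lost with the libraries rescaled to each other and in several of the fits that left out 1 library. Rps19 in VavCre Rps19flox/+ Ter119+ cytoplasm was 12020 ± 1510 against 13840 ± 1330 (-0.21 ± 0.14, adjusted p = 0.302). On polysomes Rps19 fell in VavCre Rps19flox/+ Kit+ (-0.87, adjusted p = 0.0222) and Ter119+ (-1.04, adjusted p = 0.0406). In the 1 VavCre Rpl5flox/+ Kit+ polysome library Rpl5 was 917, against 2528 ± 677 in the controls (adjusted p = 0.423). In the 3 polysome libraries labelled VavCre Rpl5flox/+ Ter119+ it was above both controls, at 547, 409.6 and 6334 against 110.2 and 226 (adjusted p = 0.096), and the last of the 3 held 1.02 M reads. The Rpl5 gene overlaps Dipk1a, and ribosomal protein genes have processed pseudogenes that can share their reads.

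Cdkn1a (chromosome 17, 29090979 to 29100722), which encodes the cell cycle inhibitor p21 and is induced by p53, separated the cytoplasm libraries by VavCre in every line. Its normalized count was 54.4 to 91 in the Kit+ cytoplasm controls, 2753 to 3315 with VavCre Rpl5flox/+ and 3719 to 5057 with VavCre Rps19flox/+. In Ter119+ cytoplasm it was 103 to 146 in the controls, 7400.4 to 8263 in the libraries labelled VavCre Rpl5flox/+ and 10944 to 11378 with VavCre Rps19flox/+.

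**Figure D1:**
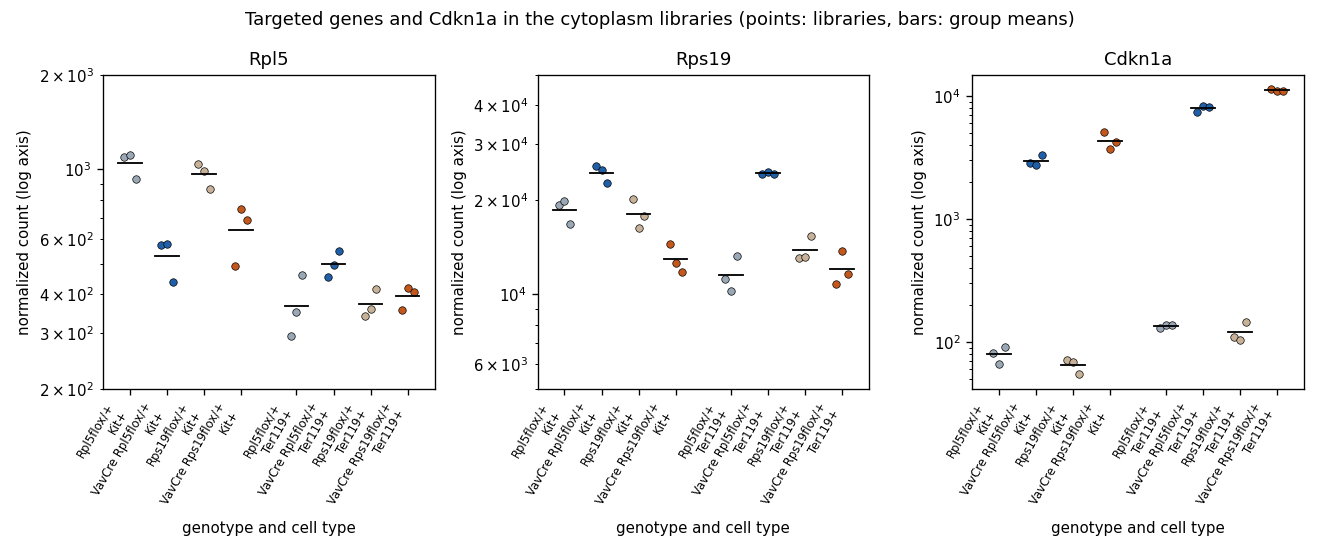
Normalized counts of Rpl5, Rps19 and Cdkn1a (log axes) in each cytoplasm library, 1 point per library and a bar at the mean of each group of 3. Rpl5 lies at 437 to 579 with VavCre Rpl5flox/+ and 930.3 to 1112 in its Kit+ controls, and Cdkn1a is at least 2753 in every VavCre library and at most 146 in every control library.

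Control Ter119+ and Kit+ cells were compared to show what separates the cell types (6 cytoplasm libraries each), and 8557 of 10867 genes tested passed, 3901 higher and 4656 lower, a balance that turned at a mean of at least 500 (2274 higher and 1175 lower). Erythroid genes were far higher in Ter119+ cells: Slc4a1 (6.16), Slc25a37 (6.14), Fech (5.01), Nfe2 (4.0) and Klf1 (2.29). Of the heme synthesis and iron uptake genes all 17 rose (median 3.0, adjusted p = 5.18e-09, or 0.311 with an estimated correlation). Of the red cell membrane genes all 20 rose (median 3.70, adjusted p = 2.61e-11, or 0.311 with an estimated correlation). Of the globins and AHSP all 9 rose (median 6.81, adjusted p = 8.63e-07, or 0.311 with an estimated correlation). Kit (-5.03), the receptor used for the first sort, Myb (-3.51) and Hmga2 (-3.37) were lower, and of the stem and progenitor genes all 20 fell (median -1.67, adjusted p = 7.78e-06, or 0.267 with an estimated correlation). Of the G2/M genes all 20 rose (median 1.55, adjusted p = 3.4e-08, or 0.311 with an estimated correlation), among them Ube2c (3.62). The ribosome biogenesis genes were lower: 1 of 34 rose and 33 fell (median -1.79, adjusted p = 1.47e-09, or 0.311 with an estimated correlation). Of the B-lymphoid markers all 10 fell (median -2.29, adjusted p = 0.0022, or 0.475 with an estimated correlation). Of the macrophage markers all 15 rose (median 2.18, adjusted p = 3.79e-05, or 0.475 with an estimated correlation).

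Polysome and cytoplasm libraries of the same control pools were compared to show which mRNAs the polysome fraction holds, in 6 Kit+ and 5 Ter119+ pools. In Kit+ cells 4824 of 10689 genes tested passed, 822 higher and 4002 lower, and the median of all genes was -1.32, or -0.39 at a mean of at least 500 and -0.87 without the libraries under 2 M reads. Ribosomal protein mRNAs were enriched on polysomes, such as Rpl38 (4.27), Rplp2 (3.86), Rps21 (3.28) and Rps28 (2.88). Of the small-subunit genes 25 of 31 rose and 1 fell (median 1.35, adjusted p = 8.25e-36, or 0.151 with an estimated correlation). Of the large-subunit genes 32 of 45 rose and 6 fell (33 up and 7 down alone, median 0.93, adjusted p = 2.05e-32, or 0.166 with an estimated correlation). Nuclear-encoded oxidative phosphorylation mRNAs were also higher, such as Ndufs5 (2.74) and Uqcrh (2.33), and 13 of 23 rose and 2 fell (14 up and 2 down alone, median 0.86, adjusted p = 3.41e-14, or 0.176 with an estimated correlation). The mitochondrially encoded mRNAs, which are translated inside mitochondria, were lower, such as mt-Nd2 (-4.88), mt-Nd1 (-4.20) and mt-Co1 (-3.49), and 1 of 13 rose and 11 fell (adjusted p = 0.000877, or 0.614 with an estimated correlation). In the polysome libraries 10.3 to 54.9% of the reads fell on Lars2 (chromosome 9, 123366927 to 123462675), which rose by 5.62. The share on Lars2 was 43, 49.4 and 54.9% in the libraries of 1.01, 1.81 and 1.83 M reads. In those of 3.64, 6.32 and 7.17 M reads it was 16.1, 12.6 and 10.3%. Whether these reads come from Lars2 mRNA was not tested. Hepatocyte markers were also higher on polysomes, and 6 of 16 rose (median 0.89, adjusted p = 1.14e-07, or 0.151 with an estimated correlation).

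In Ter119+ cells 2823 of 10588 genes tested passed, 509 higher and 2314 lower, with a median of all genes of -0.66. With the libraries rescaled to each other that median was -0.336, 1713 genes passed and 46.8% of them were higher, against 18%. The same groups stood out, with Rpl38 (2.64), Rplp2 (2.42), Rps21 (2.16) and Uqcrh (2.02) higher and mt-Nd2 (-4.51) and Pabpc1 (-2.74) lower. Of the small-subunit genes 24 of 31 rose and 1 fell (26 up and 2 down alone, median 0.92, adjusted p = 3.48e-32, or 0.116 with an estimated correlation). Of the large-subunit genes 28 of 45 rose and 3 fell (35 up and 3 down alone, median 0.78, adjusted p = 8.16e-34, or 0.0822 with an estimated correlation). Of the oxidative phosphorylation genes 16 of 23 rose (17 up and 0 down alone, median 1.04, adjusted p = 4.36e-25, or 0.0553 with an estimated correlation). Of the mitochondrially encoded mRNAs 1 of 13 rose and 12 fell (adjusted p = 7.92e-06, or 0.628 with an estimated correlation).

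VavCre Rpl5flox/+ in Kit+ cytoplasm was compared first. No group had VavCre alone, so Cre effects were not separated. Targets of p53 rose: Cdkn1a (4.99 ± 0.14, adjusted p = 3.49e-11), Zmat3 (3.95), Eda2r (3.94), Phlda3 (3.85) and Psrc1 (2.70), as did Mdm2, which encodes the ubiquitin ligase of p53 (0.76), while Trp53 itself was at -0.028. Erythroid genes were lower, among them Slc4a1, the band 3 anion exchanger (-3.04 ± 0.22, adjusted p = 6.14e-07), Epb42 (-2.10), Rhd (-1.65) and Kel (-1.28), Alas2, the first enzyme of erythroid heme synthesis (-1.74), and the transferrin receptor Tfrc (-1.04). The erythroid regulator Klf1 fell (-1.04), while Gata1 (-0.16) and Kit (-0.16) did not pass. B-lymphoid genes were lower, such as Rag1 (-2.53), Igll1 (-2.48), Cd79a (-2.47) and Vpreb3 (-2.45), and genes of granulocyte and monocyte precursors were higher, such as Ctsg (1.92), Ms4a3 (1.86), Prtn3 (1.71) and Cebpa (1.30).

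Of the p53 targets 24 of 27 rose and 2 fell (median 1.30, adjusted p = 5.62e-14, or 0.0241 with an estimated correlation). Of the heme synthesis and iron uptake genes all 17 fell (median -1.0, adjusted p = 5.86e-13, or 0.237 with an estimated correlation), among them Slc25a37 (-1.65), Abcb10 (-1.45) and Fech (-1.1). Of the red cell membrane genes 1 of 20 rose and 18 fell (median -1.2, adjusted p = 2.31e-12, or 0.237 with an estimated correlation). Of the erythroid transcription factors with Epor 8 of 17 fell (0 up and 9 down alone, median -0.17, adjusted p = 0.000918, or 0.484 with an estimated correlation), with E2f2 (-1.63), Epor (-1.02) and Tal1 (-0.86). Of the globins and AHSP 2 of 8 rose and 5 fell (median -1.05, adjusted p = 0.0386, or 0.519 with an estimated correlation), a call lost in 3 of the 6 fits that left out 1 library (highest adjusted p = 0.13, without VavCre Rpl5flox/+ replicate 3). The embryonic globin Hbb-y rose (1.97). Of the G1/S and replication genes 18 of 20 fell (0 up and 19 down alone, median -0.65, adjusted p = 8.79e-12, or 0.0787 with an estimated correlation), among them Ccne1 (-1.09), Cdc6 (-1.06) and Pcna (-0.83). Of the G2/M genes 1 of 20 rose and 11 fell (1 up and 12 down alone, median -0.36, adjusted p = 9.33e-05, or 0.178 with an estimated correlation), such as Ccnb2 (-0.75).

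Of the granulocyte and monocyte markers 13 of 18 rose (14 up and 0 down alone, median 1.26, adjusted p = 5.58e-05, or 0.484 with an estimated correlation). Of the B-lymphoid markers all 10 fell (median -2.30, adjusted p = 1.24e-08, or 0.237 with an estimated correlation). Of the stem and progenitor genes 15 of 21 rose (16 up and 0 down alone, median 0.69, adjusted p = 5.63e-05, or 0.379 with an estimated correlation), among them Cd48 (1.30), Hlf (1.08), Cd34 (0.88) and Runx1 (0.49). Ribosomal protein mRNAs were slightly higher, such as Rpl38 (0.68), Rps28 (0.65), Rpl36 (0.58) and Rps12 (0.54). Of the small-subunit genes 23 of 31 rose (27 up and 0 down alone, median 0.37, adjusted p = 3.37e-07, or 0.488 with an estimated correlation). Of the large-subunit genes 30 of 45 rose and 1 fell (32 up and 2 down alone, median 0.33, adjusted p = 1.55e-06, or 0.53 with an estimated correlation). Of the ribosome biogenesis genes 12 of 34 rose and 1 fell (median 0.18, adjusted p = 0.00762, or 0.404 with an estimated correlation). Hepatocyte markers were higher beside these groups, such as Fgb (1.64), and 15 of 16 rose (16 up and 0 down alone, median 1.39, adjusted p = 3.56e-05, or 0.519 with an estimated correlation). Of the interferon response genes 4 of 9 rose (median 0.62, adjusted p = 0.0136, or 0.404 with an estimated correlation), with Ifitm3 (2.17), Bst2 (2.15) and Isg15 (1.33). Of the oxidative phosphorylation genes 11 of 23 rose (median 0.23, adjusted p = 0.0162, or 0.682 with an estimated correlation), which was not called without Rpl5flox/+ replicate 3 (adjusted p = 0.0676). Bag1 (0.16) did not pass. The lists not called were other TOP mRNAs (7 up and 1 down of 22, adjusted p = 0.066), integrated stress response (7 up and 2 down of 18, adjusted p = 0.0904), macrophage markers (2 up and 2 down of 13, adjusted p = 0.671), megakaryocyte and platelet markers (1 up and 4 down of 11, adjusted p = 0.317), mast cell and basophil markers (4 up and 0 down of 7, adjusted p = 0.11), endothelial and stromal markers (2 up and 0 down of 10, adjusted p = 0.628), immediate early and heat shock (2 up and 3 down of 14, adjusted p = 0.293), mitochondrially encoded mRNAs (2 up and 0 down of 13, adjusted p = 0.468), sex-linked (0 up and 0 down of 4, adjusted p = 0.707) and nuclear-retained lncRNAs (0 up and 0 down of 1, adjusted p = 0.743).

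In this comparison 4055 of 10908 genes tested passed, 2267 higher and 1788 lower (limma, 3 against 3), and the libraries of the groups did not overlap for 51% of the genes tested, against 10% by chance. The balance turned at a mean of at least 500 (714 higher and 899 lower) and was near even with the libraries rescaled (2029 and 2005). With the replicate number as a block 4166 passed. The list calls rest on the preset correlation of camera, and with an estimated correlation that of the p53 targets was the only one kept.

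The effect of VavCre Rps19flox/+ in Kit+ cytoplasm addressed the small-subunit protein in the same cells. The p53 targets rose here too, with Cdkn1a (5.77 ± 0.14, adjusted p = 4.69e-12), Zmat3 (4.64), Phlda3 (4.52), Eda2r (4.0), Psrc1 (3.42) and Mdm2 (0.54), and Trp53 rose (0.98). Erythroid genes showed no called decrease in these: Klf1 (0.32), Gata1 (0.19), Alas2 (-0.10) and Slc4a1 (-0.26) did not pass, and Zfpm1 (1.33), Cbfa2t3 (1.01) and Gfi1b (0.89) rose. Granulocyte and monocyte genes fell, such as Camp (-3.14), Ly6c2 (-2.36), Irf8 (-2.26), Lyz2 (-2.05) and Csf1r (-1.57), and so did B-lymphoid genes, such as Cd79a (-3.55), Igll1 (-3.54), Vpreb3 (-3.13) and Cd79b (-2.50). Progenitor genes fell, among them Flt3 (-2.14), Hmga2 (-1.68), Cd34 (-1.63) and Fli1 (-1.40).

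Of the p53 targets 20 of 27 rose and 1 fell (median 1.35, adjusted p = 1.53e-09, or 0.0247 with an estimated correlation). Of the granulocyte and monocyte markers all 18 fell (median -2.05, adjusted p = 1.94e-09, or 0.309 with an estimated correlation). Of the B-lymphoid markers all 10 fell (median -2.81, adjusted p = 1.64e-08, or 0.237 with an estimated correlation). Of the stem and progenitor genes 16 of 21 fell (median -0.88, adjusted p = 4.21e-05, or 0.367 with an estimated correlation). Of the megakaryocyte and platelet markers 1 of 11 rose and 9 fell (median -0.86, adjusted p = 0.0064, or 0.237 with an estimated correlation), with Plek (-1.75) and Pf4 (-1.62). Of the mast cell and basophil markers 5 of 7 fell (0 up and 7 down alone, median -0.89, adjusted p = 0.012, or 0.484 with an estimated correlation), with Hdc (-1.76) and Cpa3 (-1.63). Of the erythroid transcription factors with Epor 9 of 17 rose (median 0.31, adjusted p = 0.0205, or 0.618 with an estimated correlation), a call lost without VavCre Rps19flox/+ replicate 1 (adjusted p = 0.068). Tfrc fell (-1.63), whereas Fech (0.89) and Cpox (0.78) rose, and in the red cell membrane list Aqp1 fell (-1.07).

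Ribosomal protein mRNAs were slightly lower, such as Rps12 (-0.70), Rpl17 (-0.68), Rpl23 (-0.68) and Rpl5 (-0.59), with Rpl10 higher (1.39). Of the small-subunit genes 1 of 31 rose and 25 fell (1 up and 26 down alone, median -0.32, adjusted p = 2.24e-05, or 0.565 with an estimated correlation). Of the large-subunit genes 4 of 45 rose and 24 fell (4 up and 26 down alone, median -0.24, adjusted p = 0.000848, or 0.704 with an estimated correlation). Ribosome biogenesis genes rose, such as Tcof1 (1.1) and Polr1a (1.08), and 21 of 34 rose and 4 fell (median 0.37, adjusted p = 4.83e-05, or 0.256 with an estimated correlation). The stress genes Ddit4 (3.21) and Sesn2 (2.30) rose and Atf4 fell (-0.61). Bag1 fell (-0.35). In the cell cycle lists Cenpf (-2.05), Top2a (-1.47) and Kif11 (-1.30) fell. Of the heme synthesis and iron uptake genes 4 of 17 rose and 6 fell (4 up and 7 down alone, median -0.047, adjusted p = 0.787). Of the red cell membrane genes 4 of 20 rose and 2 fell (median 0.012, adjusted p = 0.878), so neither list was called. None of the other 14 lists was called, with adjusted p from 0.0506 (nuclear-encoded oxidative phosphorylation) to 0.951 (interferon response).

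In this comparison 5859 of 10908 genes tested passed, 3012 higher and 2847 lower, and the groups did not overlap for 60.9% of the genes. The oxidative phosphorylation list passed with a replicate block (adjusted p = 0.0324), and with an estimated correlation only the p53 call was kept.

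Whether the changes of the lines differed in Kit+ cytoplasm was tested as the change with VavCre Rpl5flox/+ minus that with VavCre Rps19flox/+, each against its own controls, and 5258 of 10908 genes tested passed, 2528 higher and 2730 lower. Granulocyte and monocyte genes were higher in the difference, such as Camp (4.25), S100a9 (4.22), S100a8 (3.85), Prtn3 (3.76) and Elane (3.56), and so were progenitor genes such as Hmga2 (2.65), Cd34 (2.51), Flt3 (2.30) and Cd48 (2.28). Erythroid genes differed the other way, among them Slc4a1 (-2.78), Zfpm1 (-2.17), Fech (-1.99), Epb42 (-1.87), Kel (-1.61) and Klf1 (-1.36). Most ribosomal protein mRNAs differed upward, such as Rps12 (1.24) and Rpl38 (1.21), while Rpl10 differed downward (-1.58). Cdkn1a (-0.78), Trp53 (-1.01) and Sesn2 (-1.48) were lower in the difference.

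Counting members with a higher value for Rpl5 as risen, of the granulocyte and monocyte markers all 18 rose (median 3.07, adjusted p = 2.77e-11, or 0.295 with an estimated correlation). Of the stem and progenitor genes 18 of 21 rose (median 1.41, adjusted p = 5.55e-08, or 0.275 with an estimated correlation). Of the mast cell and basophil markers 5 of 7 rose (median 2.25, adjusted p = 0.00391, or 0.411 with an estimated correlation). Of the red cell membrane genes 19 of 20 fell (median -1.07, adjusted p = 2.46e-08, or 0.326 with an estimated correlation). Of the heme synthesis and iron uptake genes 16 of 17 fell (median -1.06, adjusted p = 8.98e-07, or 0.396 with an estimated correlation). Of the erythroid transcription factors with Epor 11 of 17 fell (0 up and 12 down alone, median -0.76, adjusted p = 5.09e-05, or 0.411 with an estimated correlation). Of the small-subunit genes 27 of 31 rose (median 0.66, adjusted p = 1.78e-09, or 0.411 with an estimated correlation). Of the large-subunit genes 31 of 45 rose and 2 fell (32 up and 2 down alone, median 0.52, adjusted p = 1e-07, or 0.487 with an estimated correlation). The p53 targets were not called as a list, with 7 of 27 higher and 6 lower (adjusted p = 0.879).

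The libraries labelled VavCre Rpl5flox/+ Ter119+ were compared with their controls. Whether the mix of sorted cells changed was not tested. The p53 targets rose, with Cdkn1a (5.72 ± 0.13, adjusted p = 3.25e-12), Zmat3 (4.94), Phlda3 (4.82), Psrc1 (2.01) and Trp53 (1.04), but Mdm2 did not pass (0.30). Erythroid genes were lower, among them Slc4a1 (-3.01 ± 0.30, adjusted p = 1.79e-06), Dmtn (-3.12), Aqp1 (-3.0), Alas2 (-2.41), Tfrc (-2.20), Klf1 (-2.19) and Gata1 (-1.53). Genes of earlier cells were higher, such as Kit (3.87), Hmga2 (2.99), Myb (2.87) and Gata2 (2.29), and so were granulocyte genes such as Ctsg (4.30), Ms4a3 (3.74), Prtn3 (3.64) and Mpo (3.09). Ribosomal protein mRNAs rose, such as Rps28 (1.57), Rps12 (1.49), Rps20 (1.48), Rpl36 (1.32) and Rps19 (1.08).

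Of the p53 targets 20 of 28 rose and 3 fell (20 up and 4 down alone, median 1.65, adjusted p = 4.21e-05, or 0.0902 with an estimated correlation). Of the heme synthesis and iron uptake genes all 17 fell (median -2.06, adjusted p = 4.08e-09, or 0.237 with an estimated correlation), among them Cpox (-2.22), Slc11a2 (-2.16) and Slc25a38 (-2.03). Of the red cell membrane genes all 20 fell (median -2.39, adjusted p = 3.69e-11, or 0.3 with an estimated correlation), such as Icam4 (-2.61) and Gypc (-2.42). Of the erythroid transcription factors with Epor 1 of 17 rose and 14 fell (median -1.70, adjusted p = 8.68e-06, or 0.298 with an estimated correlation), such as Klf3 (-2.83), Epor (-1.98) and E2f4 (-1.88). The globins were split: Hbb-y (2.14) and Hba-x (1.94) rose, and the list was not called (2 up and 6 down of 9, adjusted p = 0.199). Globin mRNAs held 28.3 to 40% of the reads, against 52 to 63.5% in all Ter119+ controls. Of the stem and progenitor genes 15 of 18 rose (median 1.61, adjusted p = 0.000174, or 0.237 with an estimated correlation). Of the granulocyte and monocyte markers 16 of 18 rose (median 2.01, adjusted p = 8.42e-05, or 0.484 with an estimated correlation). Of the mast cell and basophil markers all 5 rose (median 2.17, adjusted p = 0.0123, or 0.274 with an estimated correlation).

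Among the small-subunit genes 29 of 31 rose (median 1.03, adjusted p = 1.6e-08, or 0.463 with an estimated correlation). Among the large-subunit genes 43 of 45 rose (median 0.93, adjusted p = 5.54e-11, or 0.43 with an estimated correlation). Of the other TOP mRNAs, which also carry a 5' terminal oligopyrimidine tract, 17 of 22 rose and 2 fell (median 0.65, adjusted p = 0.00196, or 0.381 with an estimated correlation), with Npm1 (2.68) and Eef1b2 (1.65). Of the ribosome biogenesis genes 30 of 34 rose and 1 fell (median 1.62, adjusted p = 8.04e-09, or 0.331 with an estimated correlation), such as Heatr1 (2.21) and Utp20 (2.11). Of the G2/M genes 18 of 20 fell (median -1.87, adjusted p = 4.08e-09, or 0.256 with an estimated correlation), such as Ccnb2 (-2.44), Birc5 (-1.90) and Cdk1 (-1.89). Of the G1/S genes 19 of 20 fell (median -1.16, adjusted p = 2.1e-07, or 0.295 with an estimated correlation), such as Rrm2 (-2.25) and Pcna (-1.62). Of the integrated stress response genes 6 of 20 rose and 9 fell (median -0.63, adjusted p = 0.487), so the list was not called, with Ddit4 (3.33), Cebpb (2.15) and Phgdh (1.76) among those that rose. None of the other 11 lists was called, with adjusted p from 0.265 (hepatocyte markers) to 0.943 (immediate early and heat shock).

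In this comparison 7160 of 10939 genes tested passed, 3865 higher and 3295 lower, and the groups did not overlap for 71.7% of the genes. Among genes with a mean of at least 500 the balance turned, with 839 higher and 2276 lower. With the replicate number as a block 7149 passed, and with an estimated correlation none of these list calls was kept.

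VavCre Rps19flox/+ in Ter119+ cytoplasm addressed the small-subunit protein, again with the cell mix untested. The p53 targets rose, with Cdkn1a (6.39 ± 0.13, adjusted p = 7.35e-13), Zmat3 (5.22), Phlda3 (5.09), Eda2r (4.83), Psrc1 (2.11) and Trp53 (1.0). Klf1 (-0.39), Gata1 (-0.35), Alas2 (-0.34) and Slc4a1 (-0.35) did not pass, while Tfrc (-1.04) and Aqp1 (-2.29) fell. Ribosome biogenesis genes rose, such as Polr1b (1.55), Polr1a (1.48) and Nop2 (1.35). Granulocyte genes fell, such as Camp (-3.39), Ngp (-3.31), Ltf (-3.16) and S100a9 (-3.05), as did the macrophage genes Axl (-2.03), C1qa (-1.65) and Vcam1 (-1.46). Kit (2.86) and Myb (2.01) rose, whereas Cd34 (-1.88) and Flt3 (-1.5) fell.

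Of the p53 targets 19 of 28 rose and 2 fell (20 up and 2 down alone, median 1.03, adjusted p = 5.54e-11, or 0.0241 with an estimated correlation). Of the ribosome biogenesis genes 24 of 34 rose (27 up and 0 down alone, median 0.99, adjusted p = 8.17e-15, or 0.237 with an estimated correlation). Of the integrated stress response genes 2 of 20 rose and 14 fell (3 up and 14 down alone, median -0.92, adjusted p = 0.00196, or 0.404 with an estimated correlation), with Chac1 (-3.68) lower and Ddit4 (2.51) and Sesn2 (1.61) higher. Among the heme synthesis and iron uptake genes 6 of 17 fell (median -0.34, adjusted p = 0.00267, or 0.488 with an estimated correlation). Among the red cell membrane genes 5 of 20 fell (0 up and 11 down alone, median -0.47, adjusted p = 0.000139, or 0.528 with an estimated correlation). Of the G2/M genes 13 of 20 fell (0 up and 18 down alone, median -0.75, adjusted p = 3.56e-08, or 0.285 with an estimated correlation), such as Cdk1 (-0.94) and Birc5 (-0.86). Of the G1/S genes 11 of 20 fell (0 up and 13 down alone, median -0.48, adjusted p = 4.25e-06, or 0.331 with an estimated correlation), such as Pcna (-0.85) and Slbp (-0.83). Of the granulocyte and monocyte markers 13 of 18 fell (0 up and 15 down alone, median -2.13, adjusted p = 7.03e-10, or 0.297 with an estimated correlation). Of the macrophage markers 9 of 15 fell (0 up and 12 down alone, median -1.2, adjusted p = 4.84e-05, or 0.426 with an estimated correlation). Of the mast cell and basophil markers 3 of 5 fell (median -0.85, adjusted p = 0.0301, or 0.309 with an estimated correlation). Of the B-lymphoid markers 3 of 6 fell (median -1.05, adjusted p = 0.00957, or 0.309 with an estimated correlation). The ribosomal protein lists were not called (adjusted p = 0.398 and 0.892). None of the other 13 lists was called, with adjusted p from 0.167 (immediate early and heat shock) to 0.941 (interferon response).

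In this comparison 2817 of 10939 genes tested passed, 1363 higher and 1454 lower, and the groups did not overlap for 43.1% of the genes. The count was 2829 with the replicate number as a block and 1759 without VavCre Rps19flox/+ replicate 3, and with an estimated correlation the p53 call was kept and the other list calls were not.

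The difference between the lines in Ter119+ cytoplasm was tested in the same way, and 4536 of 10939 genes tested passed, 2245 higher and 2291 lower. Granulocyte genes differed, with S100a9 (5.38), Camp (5.33), S100a8 (5.16) and Ngp (5.07) higher for the libraries labelled VavCre Rpl5flox/+, followed by the mast cell genes Mcpt8 (4.07) and Hdc (4.05) and the progenitor genes Cd34 (3.70) and Cd48 (3.19). Erythroid genes differed downward, among them Slc4a1 (-2.66), Dmtn (-2.63), Zfpm1 (-2.52), Tal1 (-2.41), Klf3 (-2.37), Klf1 (-1.80) and Gata1 (-1.18). Ribosomal protein mRNAs differed upward, such as Rps20 (1.74), Rps28 (1.55), Rpl36 (1.34) and Rps19 (1.29). Cdkn1a differed by -0.66, and Kit did not pass (1.01).

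Of the granulocyte and monocyte markers all 18 rose (median 4.29, adjusted p = 6.74e-13, or 0.275 with an estimated correlation). Of the stem and progenitor genes 13 of 18 rose (14 up and 0 down alone, median 1.69, adjusted p = 5.37e-06, or 0.222 with an estimated correlation). Among the small-subunit genes 29 of 31 rose (median 1.04, adjusted p = 4.91e-12, or 0.396 with an estimated correlation). Among the large-subunit genes 41 of 45 rose (42 up and 0 down alone, median 0.99, adjusted p = 7.38e-14, or 0.396 with an estimated correlation). Among the heme synthesis and iron uptake genes 15 of 17 fell (0 up and 17 down alone, median -1.63, adjusted p = 3.32e-09, or 0.275 with an estimated correlation). Among the red cell membrane genes 19 of 20 fell (median -1.89, adjusted p = 2.55e-11, or 0.326 with an estimated correlation). Of the erythroid transcription factors with Epor 14 of 17 fell (1 up and 14 down alone, median -1.33, adjusted p = 2.59e-07, or 0.275 with an estimated correlation). Of the G2/M genes 14 of 20 fell (median -1.13, adjusted p = 1.18e-06, or 0.356 with an estimated correlation), with Ccnb2 at -1.73. The p53 targets were not called as a list (7 higher and 3 lower, adjusted p = 0.698).

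**Figure D2:**
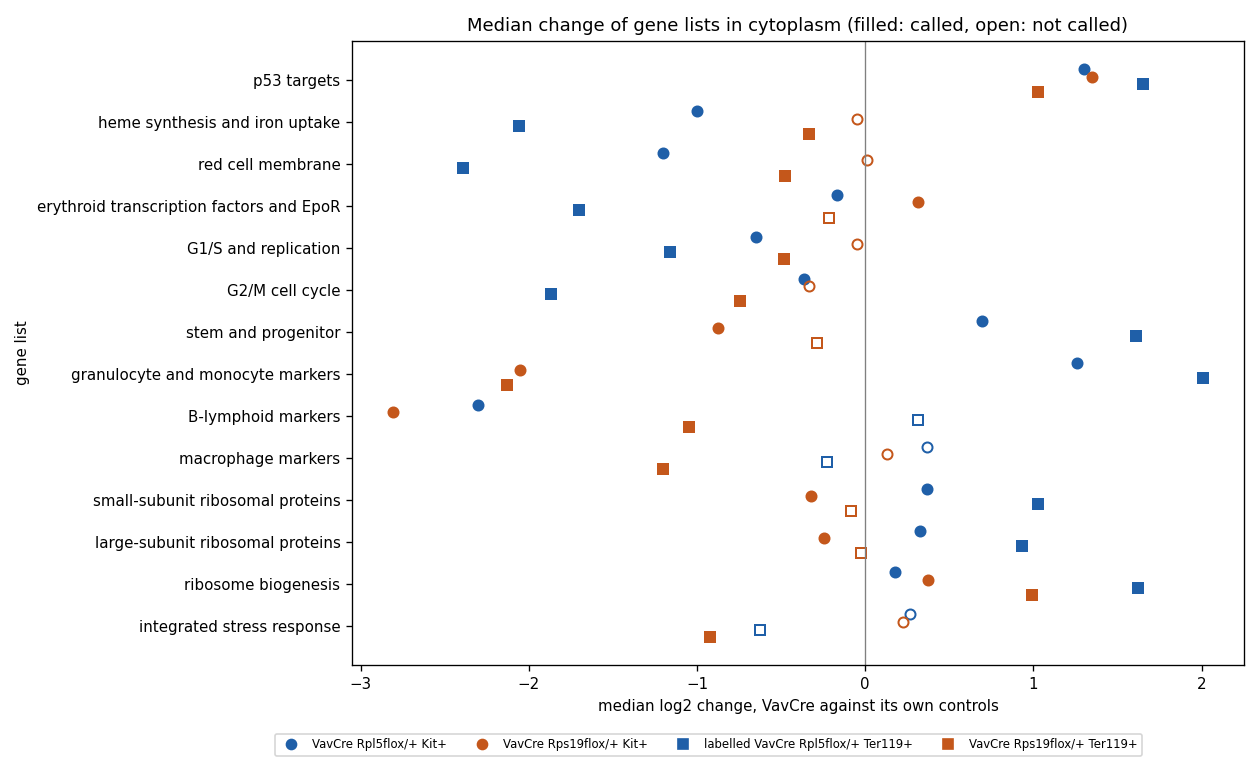
Median log2 change of the members of 14 gene lists (y axis, list names) in the 4 cytoplasm comparisons of VavCre with its own controls (x axis, log2), filled points where camera called the list at an adjusted p under 0.05 and open points where it did not. The p53 targets lie at 1.30 and 1.35 in Kit+ and at 1.65 and 1.03 in Ter119+ cells, while the granulocyte and monocyte markers lie at 1.26 and 2.01 for Rpl5 and at -2.05 and -2.13 for Rps19.

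The overlap of the calls was counted over genes, which are not independent replicates. In Kit+ cytoplasm 608 genes rose in both lines against 626 if the calls were independent, 448 fell in both against 466.7, and 1228 went opposite ways against 1085 (r = 0.075 over 10908 genes). In Ter119+ cytoplasm 1066 rose in both against 481.6, 848 fell in both against 438, and 353 went opposite ways against 924.3 (r = 0.407 over 10939 genes). Between cell types the overlap was 1652 up and 1364 down with 175 opposite for Rpl5 (r = 0.664), and 974 up and 870 down with 76 opposite for Rps19 (r = 0.669).

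**Figure D3:**
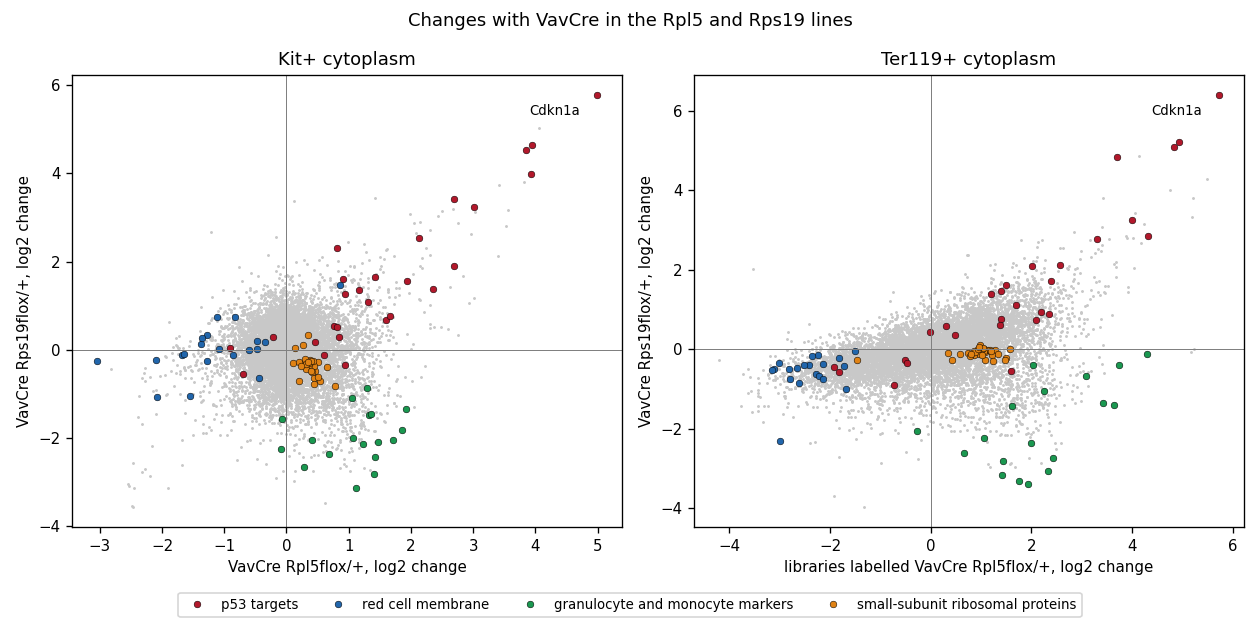
Log2 change in the libraries labelled VavCre Rpl5flox/+ (x axis) against that in those labelled VavCre Rps19flox/+ (y axis) in Kit+ and Ter119+ cytoplasm, each against its own controls, 1 grey point per gene tested and colored points for 4 gene lists. Most p53 targets lie toward the upper right in both panels, with Cdkn1a at 4.99 and 5.77 in Kit+ and 5.72 and 6.39 in Ter119+ cells, while the correlation over genes was 0.075 and 0.407.

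On polysomes the question was which mRNAs the ribosomes held in each genotype. In VavCre Rps19flox/+ Kit+ polysomes Lars2 fell (-5.86), as did ribosomal protein mRNAs such as Rpl38 (-2.93), Rplp2 (-2.58) and Rps21 (-2.08) and the granulocyte genes S100a9 (-4.09) and Mpo (-3.21). The p53 targets Plk2 (192 ± 24.2 normalized counts) and Eda2r (97.7 ± 5.74), with 0 in all 3 controls, rose, and so did the mitochondrially encoded mt-Co1 (3.18). Among the small-subunit genes 15 of 31 fell (2 up and 20 down alone, median -0.73, adjusted p = 3.01e-16, or 0.3 with an estimated correlation). Among the large-subunit genes 4 of 45 rose and 12 fell (4 up and 16 down alone, median -0.37, adjusted p = 2.1e-10, or 0.429 with an estimated correlation). In random lists of members of like abundance the medians were -0.63 and -0.57, and the small-subunit genes lay at percentile 29.9 and the large-subunit genes at percentile 90. Of the p53 targets 11 of 27 rose (18 up and 0 down alone, adjusted p = 4.84e-05, or 0.285 with an estimated correlation). Among the granulocyte and monocyte markers 5 of 18 fell (median -0.67, adjusted p = 1.66e-06, or 0.237 with an estimated correlation). That last median was -2.02 without the libraries under 2 M reads and -2.63 at a mean of at least 500, and that of the hepatocyte markers was -0.67, or 0.35 without these libraries. Of the mitochondrially encoded mRNAs 5 of 13 rose and 1 fell (7 up and 1 down alone, adjusted p = 0.00967, or 0.56 with an estimated correlation), a call lost without Rps19flox/+ replicate 2 (adjusted p = 0.154). They held 1.33 to 2.25% of the reads, against 0.208 to 0.392% in the controls. Histone mRNAs held 0.032 to 0.0538%, against 0.107 to 0.296%.

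In this comparison 1041 of 10557 genes tested passed, 653 higher and 388 lower, and the median of all genes was 1.11, or 0.19 among genes with a mean of at least 500 and 0.45 without the libraries under 2 M reads, which left 1 control library. The count was 2039 without the libraries under 2 M reads, and 2517 without Rps19flox/+ replicate 2, and 428, 362 and 371 without VavCre Rps19flox/+ replicates 1, 2 and 3. The balance turned at a mean of at least 500 (376 higher and 448 lower) and without each of the VavCre libraries (200 and 228, 163 and 199 or 171 and 200). The call of Lars2 was lost in some of the fits that left out 1 VavCre library.

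VavCre Rpl5flox/+ Kit+ polysome held 1 library, so its variation was not measured, and the p-values rest on the assumption that it varied like the other groups. In that library erythroid genes were lower than in the 3 controls, such as Slc4a1 (-3.43), Aqp1 (-3.41) and Alas2 (-3.0), none of which was called by limma voom. Among the red cell membrane genes 6 of 20 fell (0 up and 10 down alone, adjusted p = 3.01e-16, or 0.0247 with an estimated correlation). Among the heme synthesis and iron uptake genes 2 of 17 fell (0 up and 10 down alone, median -1.31, adjusted p = 4.01e-12, or 0.0241 with an estimated correlation). Among the p53 targets none of 27 passed (4 up and 0 down alone, adjusted p = 9.58e-05, or 0.287 with an estimated correlation). Among the granulocyte and monocyte markers none of 18 passed (2 up and 0 down alone, median 1.74, adjusted p = 0.000113, or 0.287 with an estimated correlation). The hepatocyte median was 1.59, at 0.616% of the reads against 0.158 to 0.226% in the controls. Under the same assumption 192 of 10557 genes tested passed, 147 higher and 45 lower. That balance was not stable, with 0 higher and 22 lower at a mean of at least 500, and 983 and 933 without the libraries under 2 M reads. The count was 314 without Rpl5flox/+ replicate 2, and by limma voom 39.

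In the polysome libraries labelled VavCre Rpl5flox/+ Ter119+ (3 against 2) erythroid genes were lower, such as Dmtn (-4.55), Slc4a1 (-4.09), Klf1 (-3.44) and Gata1 (-2.08), and Cdkn1a rose (4.68). Among the p53 targets 5 of 28 rose and 2 fell (6 up and 2 down alone, adjusted p = 0.0148, or 0.519 with an estimated correlation), with a median of -0.22, or -1.53 at a mean of at least 500 and 0.66 without the library under 2 M reads. Ribosomal protein mRNAs rose, such as Rps28 (2.87), Rps21 (2.47) and Rplp1 (2.44), as did the nucleolar protein genes Npm1 (3.28), Ncl (3.28) and Fbl (3.36) and the granulocyte genes Mpo (4.5) and Prtn3 (4.08). Among the small-subunit genes 22 of 31 rose (23 up and 0 down alone, median 1.19, adjusted p = 9.7e-29, or 0.0555 with an estimated correlation). Among the large-subunit genes 23 of 45 rose (26 up and 1 down alone, median 0.84, adjusted p = 1.99e-24, or 0.129 with an estimated correlation). Of the ribosome biogenesis genes 12 of 34 rose (18 up and 0 down alone, median 1.77, adjusted p = 4.81e-16, or 0.067 with an estimated correlation). Among the red cell membrane genes 19 of 20 fell (0 up and 20 down alone, median -3.0, adjusted p = 2.23e-20, or 0.0639 with an estimated correlation). Among the heme synthesis and iron uptake genes 15 of 17 fell (median -3.02, adjusted p = 1.69e-12, or 0.0902 with an estimated correlation). Among the erythroid transcription factors with Epor 11 of 17 fell (median -2.36, adjusted p = 1.64e-08, or 0.237 with an estimated correlation). Among the G2/M genes 15 of 20 fell (0 up and 17 down alone, median -2.48, adjusted p = 7.16e-08, or 0.12 with an estimated correlation), with Ube2c at -3.47, and of the granulocyte and monocyte markers 7 of 18 rose (median 2.07, adjusted p = 1.08e-06, or 0.3 with an estimated correlation). Hepatocyte markers moved with these, and 1 of 16 rose (median 1.67, adjusted p = 1.9e-05, or 0.456 with an estimated correlation). They held 0.169, 0.148 and 0.562% of the reads in replicates 1, 2 and 3, against a mean of 0.0288% in the controls, and without replicate 3, which held under 2 M reads, their median was 0.92. In all 1406 of 10614 genes tested passed, 314 higher and 1092 lower, with a median of all genes of -1.0, or -1.56 and -0.42 without VavCre Rpl5flox/+ replicates 2 and 3. The count was 434 and 423 without Rpl5flox/+ replicates 1 and 2, and 2407 and 2205 without VavCre Rpl5flox/+ replicates 2 and 3, and 569 with only the groups of the comparison.

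In VavCre Rps19flox/+ Ter119+ polysomes Cdkn1a rose (6.89) and Rplp1 fell (-1.68). Among the small-subunit genes 9 of 31 fell (0 up and 20 down alone, median -0.79, adjusted p = 3.38e-24, or 0.067 with an estimated correlation), at percentile 0.3 of random lists, and of the large-subunit genes 8 of 45 fell (3 up and 20 down alone, median -0.48, adjusted p = 7.33e-17, or 0.237 with an estimated correlation), at percentile 6.71. Among the p53 targets 3 of 28 rose (9 up and 0 down alone, adjusted p = 5.43e-06, or 0.287 with an estimated correlation). Among the granulocyte and monocyte markers 3 of 18 fell (0 up and 7 down alone, median -1.46, adjusted p = 2.38e-09, or 0.237 with an estimated correlation). Among the G2/M genes 3 of 20 fell (0 up and 4 down alone, median -0.34, adjusted p = 3.56e-05, or 0.237 with an estimated correlation). Only 85 of 10614 genes tested passed, 24 higher and 61 lower (limma, with 1449 at an unadjusted p under 0.05), and the median of all genes was 0.51. The count was 4, 189 and 5 without Rps19flox/+ replicates 1, 2 and 3, and 17, 5 and 4 without VavCre Rps19flox/+ replicates 1, 2 and 3, and by limma voom it was 605. Most calls were lower here, but by limma voom 340 were higher and 265 lower, with only the groups of the comparison 209 and 188, and without the libraries under 2 M reads, none of them in the comparison, 402 and 271.

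**Figure D4:**
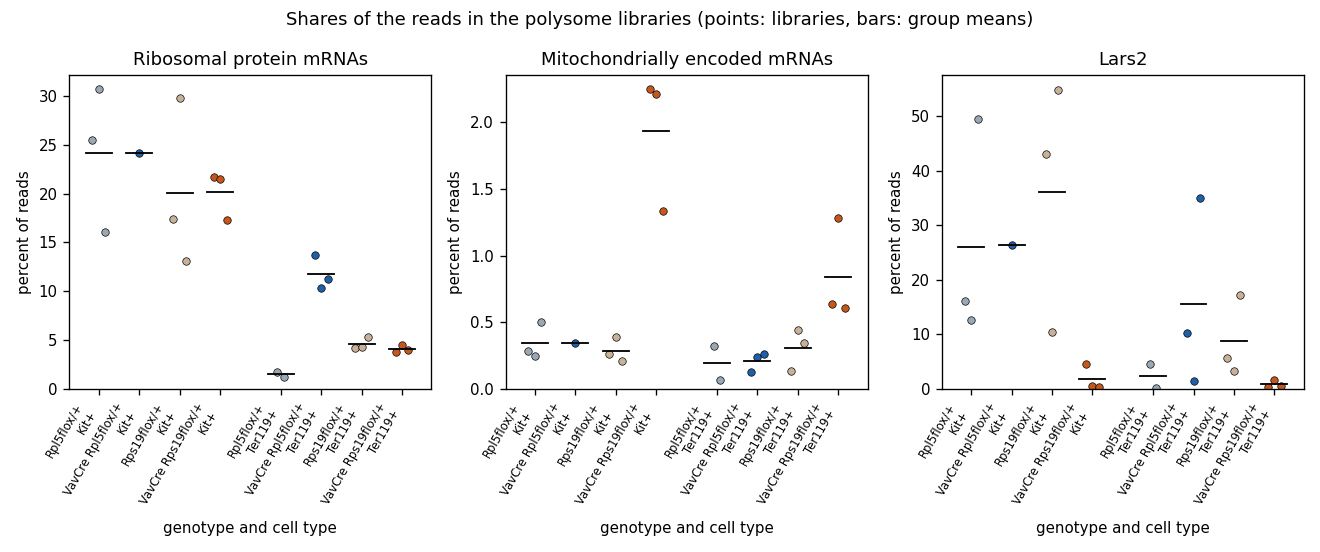
Percent of the reads of each polysome library (y axes, starting at 0) on ribosomal protein mRNAs, mitochondrially encoded mRNAs and Lars2, 1 point per library and a bar at the group mean, by genotype and cell type. Lars2 takes 10.3 to 54.9% in the Kit+ controls and 0.383 to 4.51% with VavCre Rps19flox/+, and the mitochondrially encoded mRNAs take 0.208 to 0.499% and 1.33 to 2.25%.

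The change of the polysome to cytoplasm ratio was tested to ask whether the loading of an mRNA moved apart from its level. With VavCre Rps19flox/+ in Kit+ cells the ratio fell for Rpl38 (-2.39), Rplp2 (-2.09), Fbl (-2.01), Tcof1 (-2.93) and Lars2 (-4.39), and rose for mt-Co1 (3.17). For the small-subunit genes 9 of 31 fell (2 up and 11 down alone, median -0.35, adjusted p = 3.73e-09, or 0.845 with an estimated correlation), at percentile 12.5 of random lists. Of the ribosome biogenesis genes 4 of 34 fell (1 up and 7 down alone, median -0.39, adjusted p = 1.75e-07, or 0.0629 with an estimated correlation). In all 921 of 10819 genes tested passed, 629 higher and 292 lower, with a median of all genes of 1.19, or 0.49 without the libraries under 2 M reads and 0.36 at a mean of at least 500. The balance turned at that mean (338 higher and 373 lower) and without each of the VavCre pools (24 and 69, 29 and 65 or 26 and 63). The count was 444, 2599 and 485 without Rps19flox/+ replicates 1, 2 and 3, and 93, 94 and 89 without VavCre Rps19flox/+ replicates 1, 2 and 3, each leaving out both libraries of 1 pool, and the mt-Co1 and Lars2 calls were lost in some of these fits.

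With VavCre Rps19flox/+ in Ter119+ cells 2 of 10898 genes tested passed, 1 higher and 1 lower (limma, 1114 at an unadjusted p under 0.05, and 69 by limma voom). For the small-subunit genes none of 31 passed (0 up and 15 down alone, median -0.59, adjusted p = 3.22e-24, or 0.525 with an estimated correlation), at percentile 0.01 of random lists, and of the large-subunit genes 1 of 45 fell (1 up and 16 down alone, median -0.45, adjusted p = 3.98e-20, or 0.642 with an estimated correlation), at percentile 0.01. Of the called genes Rplp1 fell (-1.59, adjusted p = 0.0419), and the other was Gm49342. The count was 1, 30 and 1 without Rps19flox/+ replicates 1, 2 and 3, and 1, 1 and 1 without VavCre Rps19flox/+ replicates 1, 2 and 3, 233 without the libraries under 2 M reads and 23 without the block of pools.

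With VavCre Rpl5flox/+ in Kit+ cells, where 1 pool was set against 3, 31 of 10819 genes tested passed, 24 higher and 7 lower. For the small-subunit genes none of 31 passed (median -0.45, adjusted p = 2.69e-10, or 0.845 with an estimated correlation), at percentile 0.03 of random lists. The count was 8 and 53 without Rpl5flox/+ replicates 1 and 3, 1021 without the libraries under 2 M reads, 170 without the block of pools and 0 by limma voom. In the libraries labelled VavCre Rpl5flox/+ Ter119+ (3 against 2) Gm49342 was the 1 gene called (limma, 1586 at an unadjusted p under 0.05, 2 by limma voom), and the count was 0 and 0 without Rpl5flox/+ replicates 1 and 2, and 828 without VavCre Rpl5flox/+ replicate 2.

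The lines also differed on Ter119+ polysomes, where 1100 of 10614 genes tested passed, 271 higher and 829 lower, with a median of all genes of -1.67, or -0.99 without VavCre Rpl5flox/+ replicate 3. Ribosomal protein mRNAs were higher in the difference, such as Rps28 (4.46), Rps21 (4.22) and Rplp1 (4.12), and so were the granulocyte genes S100a9 (7.0), S100a8 (6.75) and Mpo (5.90), while erythroid genes were lower, such as Gypc (-5.65), Tal1 (-5.28), Zfpm1 (-5.25), Fech (-4.59), Slc4a1 (-4.21) and Klf1 (-3.70). For the small-subunit genes 23 of 31 rose (26 up and 0 down alone, median 1.91, adjusted p = 1.67e-37, or 0.0605 with an estimated correlation). Among the large-subunit genes 23 of 45 rose and 2 fell (25 up and 3 down alone, median 1.5, adjusted p = 4.38e-30, or 0.182 with an estimated correlation). Among the heme synthesis and iron uptake genes 13 of 17 fell (1 up and 14 down alone, median -3.57, adjusted p = 9.4e-09, or 0.216 with an estimated correlation). Among the red cell membrane genes 16 of 20 fell (0 up and 17 down alone, median -3.21, adjusted p = 2.29e-13, or 0.182 with an estimated correlation). Among the granulocyte and monocyte markers 6 of 18 rose (7 up and 0 down alone, median 2.97, adjusted p = 3.37e-11, or 0.246 with an estimated correlation). The count was 435 and 422 without Rpl5flox/+ replicates 1 and 2, 653 and 656 without Rps19flox/+ replicates 1 and 3, 2371 and 2390 without VavCre Rpl5flox/+ replicates 2 and 3, and 631, 623 and 691 without VavCre Rps19flox/+ replicates 1, 2 and 3, and 2390 without the libraries under 2 M reads.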

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

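The tests of mixed fractions, of exchanged fractions, of an exchange with controls and of a lower share of erythroid cells were chosen only after the results were seen. Besides 3 patterns, this part gives the results for which a difference between the lines or between the fractions was itself tested and passed. Groups held at most 3 libraries, so a test for an outlying library, which needs 4, was not applied.

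In VavCre Rps19flox/+ Kit+ polysomes the medians of the mitochondrially encoded mRNAs and of all genes were higher than in the controls, though 5 of these 13 mRNAs rose, 1 fell and the list call was lost with an estimated correlation (adjusted p = 0.56) and without Rps19flox/+ replicate 2 (0.154), and the ribosomal protein share, taken without Lars2, was at least 5.44% of reads higher than in the cytoplasm library of each of the 3 pools, which argues against exchanged fractions. After the VavCre libraries were thinned to the size factors of the controls the medians were 2.01 and 0.996, with 2 members that were at 0 in a group kept at their fitted values, against 2.02 and 1.11 before, or 2.03 and 1.06 when thinned to the controls' reads, which argues against a difference in depth as the whole cause. Without the libraries under 2 M reads, which left 1 control library, they were 1.60 and 0.446, so a part of the shift of all genes stays open. Cytoplasmic RNA carried into the polysome fraction stays open, since the mixing shares from mitochondrial and ribosomal protein mRNAs, taken without Lars2, differed by 1.38 in replicate 1 but by 0.0251 and -0.375 in replicates 2 and 3, and shares first taken with Lars2 left it open too. A change in the handling of these mRNAs with less RPS19 may be named only as a hypothesis and was not tested.

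Rpl5 was higher in the libraries labelled VavCre Rpl5flox/+ Ter119+ cytoplasm than in the controls. The lowest of these libraries had 53.4 times the Cdkn1a of the highest control library, which argues against an exchange of libraries with the controls. A rise shared by the large-subunit mRNAs stays open. Of the 45 other members 4.44% lay below Rpl5, or 2.22 to 6.67% within 1 standard error. Without the error, added after the share was seen, the bound set against this (5% or less) would have been met. That bound cannot decide, since a shared rise with 1 copy lost also puts Rpl5 low. Cells with both copies, as in the controls, cannot alone raise Rpl5 above them.

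In VavCre Rpl5flox/+ Kit+ cytoplasm erythroid genes were lower and granulocyte and monocyte genes higher. With an estimated correlation the list calls were lost (adjusted p = 0.484 for granulocyte and monocyte, 0.237 for heme and 0.237 for red cell membrane genes), and 15 of 16 hepatocyte markers rose too (median 1.39). The B-lymphoid median minus the granulocyte and monocyte median was -3.56, which argues against a loss of erythroid cells alone. A joint loss of B cells stays open. With the libraries rescaled the granulocyte and monocyte median was 1.22, but rescaling moves all lists alike and cannot test scaling. A shift in the types or stages of the Kit+ cells, or in what each cell expresses, may underlie the pattern, and neither was tested.

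Splits of the libraries into other groups were too few for a share under 0.05 in the comparisons of 3 against 3, which have 10 splits. The real split called 4055, 5859, 7160 and 2817 genes in cytoplasm (Rpl5 and Rps19 in Kit+, then in Ter119+ cells), 1041 and 85 on polysomes and 921 and 2 for the ratios of Rps19, and the highest other split called 0 in each. The same holds for polysome against cytoplasm in Ter119+ controls, with 16 splits, 2823 genes and at most 0 otherwise. In Kit+ controls 1 of 32 splits gave as many as 4824 genes, the highest other being 0, and for Ter119+ against Kit+ cells 1 of 100 gave as many as 8557, the highest other being 4964, so chance can be excluded in both. For the difference between the lines in Ter119+ cytoplasm 3 of 100 splits gave as many as 4536 genes, the highest other being 5341. In Kit+ cytoplasm 11 of 100 gave as many as 5258, the highest other being 6077. Besides the real split these were 2 of 9 and 10 of 12 splits that moved control libraries only, which leave the VavCre libraries of the lines apart. Splits that moved VavCre libraries called at most 1 and 0, so both results show the same pattern. The share of splits thus depends on how many that moved controls only were drawn, and it cannot decide on chance in either cell type.

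Between the lines 5258 genes differed in Kit+ cytoplasm, 4536 in Ter119+ cytoplasm and 1100 on Ter119+ polysomes. Between the fractions the effect differed for 31 genes (Rpl5) and 921 (Rps19) in Kit+ cells, and for 1 (Rpl5) and 2 (Rps19) in Ter119+ cells. None of the list calls that follow was kept with an estimated correlation (limma camera, adjusted p = 0.0605 to 0.845). Of the lists given in the report, the medians that differed between the lines in Kit+ cytoplasm were small-subunit ribosomal proteins 0.66, large-subunit ribosomal proteins 0.52, heme synthesis and iron uptake -1.06, red cell membrane -1.07, erythroid transcription factors and EpoR -0.76, stem and progenitor 1.41, granulocyte and monocyte markers 3.07 and mast cell and basophil markers 2.25. In Ter119+ cytoplasm they were small-subunit ribosomal proteins 1.04, large-subunit ribosomal proteins 0.99, heme synthesis and iron uptake -1.63, red cell membrane -1.89, erythroid transcription factors and EpoR -1.33, stem and progenitor 1.69, G2/M cell cycle -1.13 and granulocyte and monocyte markers 4.29, and on Ter119+ polysomes small-subunit ribosomal proteins 1.91, large-subunit ribosomal proteins 1.5, heme synthesis and iron uptake -3.57, red cell membrane -3.21 and granulocyte and monocyte markers 2.97. Between the fractions the medians were small-subunit ribosomal proteins -0.35 and ribosome biogenesis -0.39 for Rps19 in Kit+ cells, where the small-subunit median lay at percentile 12.5 of random lists, and small-subunit ribosomal proteins -0.59 and large-subunit ribosomal proteins -0.45 for Rps19 in Ter119+ cells. For Rpl5 in Kit+ cells it was small-subunit ribosomal proteins -0.45, which rests on 1 VavCre pool, and no gene was called there by limma voom or with only the groups of the comparison.

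The named genes that differed between the lines in Kit+ cytoplasm, as log2 differences, were Camp 4.25, Cd34 2.51, Cd48 2.28, Cdkn1a -0.78, Elane 3.56, Epb42 -1.87, Fech -1.99, Flt3 2.30, Hmga2 2.65, Kel -1.61, Klf1 -1.36, Prtn3 3.76, Rpl10 -1.58, Rpl38 1.21, Rps12 1.24, S100a8 3.85, S100a9 4.22, Sesn2 -1.48, Slc4a1 -2.78, Trp53 -1.01 and Zfpm1 -2.17. In Ter119+ cytoplasm they were Camp 5.33, Ccnb2 -1.73, Cd34 3.70, Cd48 3.19, Cdkn1a -0.66, Dmtn -2.63, Gata1 -1.18, Hdc 4.05, Klf1 -1.80, Klf3 -2.37, Mcpt8 4.07, Ngp 5.07, Rpl36 1.34, Rps19 1.29, Rps20 1.74, Rps28 1.55, S100a8 5.16, S100a9 5.38, Slc4a1 -2.66, Tal1 -2.41 and Zfpm1 -2.52. On Ter119+ polysomes they were Fech -4.59, Gypc -5.65, Klf1 -3.70, Mpo 5.90, Rplp1 4.12, Rps21 4.22, Rps28 4.46, S100a8 6.75, S100a9 7.0, Slc4a1 -4.21, Tal1 -5.28 and Zfpm1 -5.25. Between the fractions they were Fbl -2.01, Lars2 -4.39, mt-Co1 3.17, Rpl38 -2.39, Rplp2 -2.09 and Tcof1 -2.93 for Rps19 in Kit+ cells and Rplp1 -1.59 for Rps19 in Ter119+ cells.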

How the results depend on the processing

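Of 21908 gene results under an alternative, over all genes the naming rule takes, 20438 kept direction and side of the threshold, 1322 lost the call, 60 gained it and 88 changed sign. The methods give the alternatives added after seeing the data and the planned fits that were not run. Rpl5 in Kit+ polysome and in Kit+ ratio could not be fitted without the 1 VavCre library. Where no cause is named below, the cause was not tested.

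Counts that moved by over 1.5 times were as follows. At a mean of at least 500, where fewer genes were tested, they were 1613 in Rpl5 Kit+ cytoplasm, 2298 in Rps19 Kit+ cytoplasm, 22 in Rpl5 Kit+ polysome, 3115 in Rpl5 Ter119+ cytoplasm, 1091 in Rps19 Ter119+ cytoplasm, 178 in Rps19 Ter119+ polysome, 1 in Rpl5 Kit+ ratio, 1899 in Kit+ control fractions, 3449 in Ter119+ against Kit+, 2141 in the difference in Kit+ cytoplasm and 2400 in the difference in Ter119+ cytoplasm. Without a filter they were 502 in Rpl5 Kit+ polysome, 2248 in Rps19 Kit+ polysome and 263 in Rpl5 Kit+ ratio. With only the groups of the comparison they were 570 in Rpl5 Kit+ polysome, 569 in Rpl5 Ter119+ polysome, 397 in Rps19 Ter119+ polysome, 0 in Rpl5 Kit+ ratio, 1432 in Rps19 Kit+ ratio and 0 in Rpl5 Ter119+ ratio. With libraries rescaled they were 1 in Rps19 Ter119+ ratio and 1713 in Ter119+ control fractions. By voom they were 39 in Rpl5 Kit+ polysome, 2155 in Rps19 Kit+ polysome, 605 in Rps19 Ter119+ polysome, 0 in Rpl5 Kit+ ratio, 2 in Rpl5 Ter119+ ratio, 69 in Rps19 Ter119+ ratio and 1994 in the difference in Ter119+ polysome. With log2 of the count plus 1 it was 52 in Rpl5 Kit+ ratio. Without the libraries under 2 M reads they were 1916 in Rpl5 Kit+ polysome, 2039 in Rps19 Kit+ polysome, 2205 in Rpl5 Ter119+ polysome, 673 in Rps19 Ter119+ polysome, 1021 in Rpl5 Kit+ ratio, 233 in Rps19 Ter119+ ratio and 2390 in the difference in Ter119+ polysome. Without the block of pools they were 170 in Rpl5 Kit+ ratio, 1780 in Rps19 Kit+ ratio, 3 in Rpl5 Ter119+ ratio and 23 in Rps19 Ter119+ ratio.

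With 1 library left out in turn, or 1 pool for ratios and fractions, the counts were 259 to 314 in Rpl5 Kit+ polysome, 362 to 2517 in Rps19 Kit+ polysome, 1759 to 2863 in Rps19 Ter119+ cytoplasm, 423 to 2407 in Rpl5 Ter119+ polysome, 4 to 189 in Rps19 Ter119+ polysome, 8 to 53 in Rpl5 Kit+ ratio, 89 to 2599 in Rps19 Kit+ ratio, 0 to 828 in Rpl5 Ter119+ ratio, 1 to 30 in Rps19 Ter119+ ratio, 1685 to 2324 in Ter119+ control fractions and 422 to 2390 in the difference in Ter119+ polysome. In Ter119+ control fractions the count was 1788 without Rpl5flox/+ replicate 2, and 1685 without Rps19flox/+ replicate 1. Which direction held more genes also turned without 1 library in Rps19 Kit+ cytoplasm (2836 and 2872 without VavCre Rps19flox/+ replicate 2), in Rps19 Ter119+ cytoplasm (1145 and 1006 without Rps19flox/+ replicate 1, 998 and 987 and 888 and 871 without VavCre Rps19flox/+ replicates 2 and 3) and in the differences in cytoplasm, where higher and lower were near even.

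In comparisons that the numbers did not pair, a replicate block gave 5980 genes in Rps19 Kit+ cytoplasm against 5859, 789 genes in Rps19 Kit+ polysome against 1041, 1063 genes in Rpl5 Ter119+ polysome against 1406 and 82 genes in Rps19 Ter119+ polysome against 85, and 79 in Rpl5 Kit+ polysome against 192. A block within each line gave 92 in Rpl5 Kit+ polysome, 451 in Rps19 Ter119+ polysome and 2139 in the difference in Ter119+ polysome. The block added, or left out of ratios and fractions, changed 15 list calls, given as adjusted p with the original first: interferon response in Ter119+ against Kit+ (0.0506, 0.0494), other TOP mRNAs in Ter119+ against Kit+ (0.0483, 0.0533), interferon response in the difference in Kit+ cytoplasm (0.056, 0.0439), stem and progenitor in the difference in Ter119+ polysome (0.0549, 0.0472), granulocyte and monocyte markers in Kit+ control fractions (0.0367, 0.0883), erythroid transcription factors and EpoR in Ter119+ control fractions (0.0367, 0.0903), granulocyte and monocyte markers in Ter119+ control fractions (0.0447, 0.127), large-subunit ribosomal proteins in Rpl5 Kit+ polysome (0.558, 0.00138), nuclear-encoded oxidative phosphorylation in Rpl5 Kit+ polysome (0.209, 0.00377), small-subunit ribosomal proteins in Rpl5 Kit+ polysome (0.3, 0.000119), stem and progenitor in Rpl5 Ter119+ polysome (0.0551, 0.0429), large-subunit ribosomal proteins in Rpl5 Ter119+ ratio (0.0468, 0.0896), nuclear-encoded oxidative phosphorylation in Rps19 Kit+ cytoplasm (0.0506, 0.0324), heme synthesis and iron uptake in Rps19 Ter119+ ratio (0.019, 0.0529) and red cell membrane in Rps19 Ter119+ ratio (0.0366, 0.14). Of the genes named, Klf1 in Rps19 Kit+ cytoplasm passed with it by limma (0.32, adjusted p = 0.0378) and Alas2 in Rpl5 Kit+ polysome no longer did (-2.97, adjusted p = 0.0791), and it changed no other call of a named gene.

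Signs changed for 2 named genes in fits without 1 library, none of which passed (limma, lowest adjusted p = 0.659). Trp53 in Rpl5 Kit+ cytoplasm was 0.080 without Rpl5flox/+ replicate 3 and 0.052 without VavCre Rpl5flox/+ replicate 1. Alas2 in Rps19 Kit+ cytoplasm was 0.11 without Rps19flox/+ replicate 1 and 0.099 without VavCre Rps19flox/+ replicate 2. Over all such fits the ranges were -0.11 to 0.080 for Trp53 and -0.35 to 0.11 for Alas2. Of 191 list calls in 468 tests, 190 were also made with a pseudocount of 5, 5 with an estimated correlation and 133 by fry. On polysomes, with 4 libraries under 2 M reads, simulated changes of 1 were recovered for at most 5.97% of genes. The parts owed to depth and spread were not separated. With the VavCre Rps19flox/+ Kit+ polysome libraries thinned to the depths of the controls, 935 or 779 genes were called, against 1041.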

Other observations

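Reads of Rps27 and Rps27rt, a near-identical copy of its coding sequence, were split unevenly. Rps27rt held 39 to 89.1% of the sum on VavCre Rps19flox/+ Kit+ polysomes, 0% on other Kit+ polysomes and 33.1 to 96.2% in Kit+ cytoplasm. Carry-over was not tested on this, and neither gene is named with a change.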
